A study of Rattus norvegicus with 6 samples.

How the data were processed

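The measurement was the RNA of rat renal cortex on Agilent 1-colour oligonucleotide microarrays, with 1 array per animal and 6 arrays in all. Per the labels' protocols, total RNA was labelled with the dye Cy3 through amplified cRNA, and 3 male Sprague-Dawley rats received corn oil while 3 received chlorothalonil, for 4 weeks. The series design text calls the 3 samples of each group biological replicates. The scanner's spot brightness was deposited as an intensity on a linear scale, and per the file headers it was extracted with Agilent Feature Extraction, which the submitters' processing notes give as version 10.7. The intensity used here, the processed signal, had its background subtracted and spatial trends removed within each array, per the file headers, and carried no scaling between arrays. The authors' deposited value table holds a ratio: each array's processed signal divided by 1 constant per array, close to that array's 75th percentile. No label states that scaling, which was found by dividing the processed signals by the table, so it is on a linear scale and not centred across arrays. Its column medians were 0.107, 0.109 and 0.112 for corn oil replicates 1 to 3 and 0.105, 0.105 and 0.106 for chlorothalonil replicates 1 to 3. How the authors chose spots for that constant is not given in the sources used here.

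Each array held 62976 spots, of which 61537 were probes other than control spots. Between 38234 and 41711 of these probes per array were well above background, the lowest number being that of corn oil replicate 3. No probe was saturated, and 0 to 9 spots per array were marked as outliers and left out. The number of arrays limits the precision of every value below.

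The main values were log2 of the processed signal minus each array's 75th percentile of it over the probes other than controls. A probe was kept if it was well above background on all 3 arrays of at least 1 group and measured on at least 2 arrays per group, which left 39862 probes. Probes were named by their accession, without versions, through a RefSeq gene table of assembly GRCr8. The array headers name an older rat build, so no coordinates are given. Of the 61537 probes, 28206 matched 1 gene, for 15645 gene symbols, and the other 33331 keep the identifier of the file. Where several kept probes measured 1 gene, the brightest on average was taken, and for the genes named whose probes spread most the range over probes is given beside them. This gave 29115 features, of which 11926 had a gene symbol.

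The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with no covariate and a Benjamini-Hochberg adjusted p of 0.05 as the threshold. Fold changes are chlorothalonil minus corn oil. Adjusted p-values in the text are from this limma fit unless another test is named. The 30 fixed gene lists were tested with camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 29 lists that had at least 5 measured members. The design, the alternatives, the gene lists and the rule for the genes named were set before the data were examined. The rule took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and which were well above background on all 6 arrays and had a gene symbol other than a predicted-locus name. It also took up to 4 members past the threshold from each list, or the member with the smallest p where none passed. Lastly, it took up to 3 genes per direction that were past the threshold and not well above background on any array of 1 group. For these a bound is given: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal. A few genes that this rule takes are not reported here.

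All 3 corn oil arrays lay on 1 slide and all 3 chlorothalonil arrays on another, scanned on different days. Slide and treatment therefore cannot be told apart, and the planned model with the slide as a block could not be fitted. The labels of chlorothalonil replicate 3 disagree: its source name states ethylenediamine dihydrochloride, while its title, treatment and dose labels and the treatment protocol state chlorothalonil. It was kept in the chlorothalonil group, and the leading counts are also given without it.

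The alternatives were quantile normalization, scaling to the array median, the deposited value table, 2 other filters on dim probes, outlier spots kept, the mean of a gene's probes, a variance prior with trend and robust fitting, the replicate number as a block, each array left out in turn, and camera with an estimated correlation and fry for the lists. A planned background correction by normexp used the mean spot signal, a column these files do not have. It was run on the median spot signal and its background with an offset of 50, an alternative chosen after seeing the data. The count of listed NRF2 genes per setting was also added after seeing the data.

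The fit was tested on simulated data drawn from the real means and spreads of 29109 features, with 200 changed in each of 10 runs. It recovered 21.5% of features changed 1.41-fold, 65.5% of those changed 2-fold and 87.1% of those changed 4-fold, and 4.06% of its calls were false. A list shifted by 1 on the log2 scale was called by camera in 10 of 10 runs, with 1 call of another list over all runs. The simulated features varied independently of each other, so these runs cannot show how often camera calls lists of correlated genes. On the real arrays the estimated correlation was 0.159 for the NRF2 and glutathione list and 0.421 for the oxidative phosphorylation list.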

Results

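Gene expression was measured in the renal cortex, the outer part of the kidney that holds the glomeruli and most of the proximal tubules. The male Sprague-Dawley rats were 5 weeks old when obtained. Of these animals, 3 received corn oil as the vehicle control, and another 3 received chlorothalonil, a chlorinated nitrile fungicide, at 500 mg/kg/day for 4 weeks. Each animal gave 1 array. The share of probes well above background was 66.3%, 66.8% and 62.1% in corn oil replicates 1 to 3 and 67.7%, 67.8% and 66.6% in chlorothalonil replicates 1 to 3. Pearson's r across 29115 features lay between 0.994 and 0.995 among the chlorothalonil arrays, between 0.988 and 0.992 among the corn oil arrays, and between 0.986 and 0.990 across the groups. These r values are across genes, which are not independent replicates. The design asks which genes of the renal cortex differ after chlorothalonil.

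With chlorothalonil against corn oil, Gstm1, a glutathione S-transferase that joins glutathione to reactive compounds, rose by 6.43 ± 0.75 (SE) on the log2 scale, which is 86.5-fold. Nqo1, a quinone reductase, rose by 4.33 ± 0.43, or 20.1-fold, and Gstp1, another glutathione S-transferase, by 2.93 ± 0.14, or 7.60-fold. Among the falls, Ptgds, a prostaglandin D synthase, had a log2 fold change of −1.71 ± 0.24. Slc31a1, the high-affinity copper importer, had one of −1.04 ± 0.09. Of 29115 features, 909 changed at an adjusted p of 0.05 in limma, 378 higher and 531 lower with chlorothalonil, and 211 of them changed at least 2-fold. Scaling to the array median in place of the 75th percentile turned the balance, with 435 higher and 368 lower of 803. The 3 arrays of one group all lay above those of the other for 8057 features, 27.7% of those tested, where chance gives 10%. An unadjusted limma p under 0.05 was reached by 5748 of the 29115 features, and by 2215 of the 11926 with a gene symbol. Counts at that level in the gene lists below are to be read against these shares. Of the features with a gene symbol, 255 of 11926 changed, 172 higher and 83 lower. Of those without one, 654 of 17189 changed, 206 higher and 448 lower.

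The number of changed features depended on every array. It was 388, 292 and 232 without corn oil replicates 1, 2 and 3, and 112, 142 and 182 without chlorothalonil replicates 1, 2 and 3. Chlorothalonil replicate 3 is the array whose source name gives another compound. Without it, 82 features were higher and 100 lower, 100 of the changed features changed at least 2-fold, and 163 of the 182 were among the 909. Of the 909, 75 passed the threshold in all 6 of these fits, 42 higher and 33 lower. Each group lay on a slide of its own, scanned on a day of its own, so treatment and slide cannot be told apart in any value given here.

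**Figure D1:**
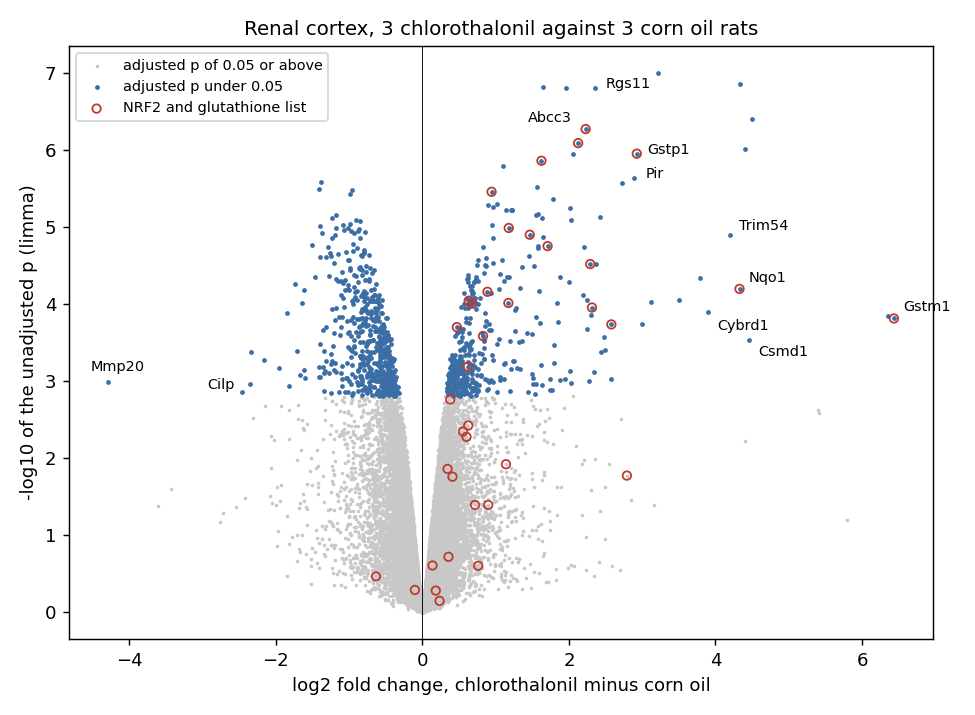
Each point is 1 of the 29115 features, with its log2 fold change (chlorothalonil minus corn oil) on the x axis and −log10 of the unadjusted limma p on the y axis. Blue points are the 909 features past the adjusted threshold, and red rings mark the 37 measured NRF2 and glutathione genes, 20 of which are higher and 0 lower.

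The 12 largest rises among genes past the threshold and measured on all 6 arrays without overlap of the groups included Gstm1, Gstp1 and 3 UDP-glucuronosyltransferases, which attach glucuronic acid to foreign compounds. The log2 signal of Gstm1, relative to the array's 75th percentile, was 7.51 ± 0.47 (SD, n = 3) with chlorothalonil and 1.07 ± 1.50 with corn oil, where corn oil replicate 1 lay at −0.64 and the other two at 1.67 and 2.18. Ugt2b15, Ugt2b35 and Ugt2b37 rose by 3.50 ± 0.37 (SE), 3.11 ± 0.33 and 3.00 ± 0.36. Glutathione transferases and these UDP-glucuronosyltransferases belong to families of near-identical genes, so how much of each signal belongs to the gene named is uncertain. Another UDP-glucuronosyltransferase, Ugt2b7, chosen after its value was seen, was at 5.40 ± 1.06 and did not pass, with an adjusted p of 0.063. Cybrd1, a ferric reductase, rose by 3.90 ± 0.44, Pir, an iron-binding nuclear protein, by 2.89 ± 0.16, and Srxn1, which restores oxidised peroxiredoxins, by 2.58 ± 0.31. Camk2b, a calmodulin-dependent kinase subunit, rose by 2.44 ± 0.34, Ltbp2, a matrix protein that binds microfibrils, by 2.43 ± 0.17, and Rgs11, a regulator of G protein signalling, by 2.35 ± 0.08. The probes of Rgs11 disagreed, with log2 fold changes from −0.13 to 2.35. Several other rises were higher than corn oil on each kept probe but differed in size between probes. The range was 3.80 to 4.33 for Nqo1, 2.29 to 3.90 for Cybrd1, 3.50 to 4.17 for Ugt2b15 and 3.00 to 3.96 for Ugt2b37. It was 2.93 to 4.46 for Gstp1, 1.72 to 2.58 for Srxn1, 1.30 to 2.44 for Camk2b and 2.22 to 2.87 for Ltbp2. Chlorothalonil replicate 3 had the lowest treated signal for Nqo1, 0.21 against 1.47 and 1.77, and for Cybrd1, 1.65 against 3.47 and 2.69. For Gstm1 its signal of 7.55 lay between those of the other two.

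The largest falls were smaller. Cilp, a cartilage matrix protein, had a log2 fold change of −2.35 ± 0.39 (SE) and was followed by Ptgds. Clcn1, a chloride channel of skeletal muscle, had −1.40 ± 0.19 and Dnm3, a dynamin, −1.36 ± 0.21, with probes from −1.46 to −0.92. The transcription factor Etv4 had −1.28 ± 0.20, and Mlph, an adaptor of vesicle transport, −1.20 ± 0.18. Ppp1r14bl had −1.01 ± 0.07 and Samd12 −0.93 ± 0.13. The phosphatase Dusp2 fell from −3.31 ± 0.19 (SD, n = 3) with corn oil to −4.31 ± 0.27 with chlorothalonil. Clcn1 and Etv4 were also dim, both at −3.6 with corn oil and at −5.0 and −4.9 with chlorothalonil. A dim spike-in probe, which matches no rat RNA, differed by −0.342 between the slides. Part of the falls of such dim genes may therefore be by slide, which was not tested. Fhl3 had −1.23 ± 0.14 on its brighter probe and −0.04 on its other one. Without corn oil replicates 1, 2 or 3 the other probe was the brighter, and without corn oil replicate 2 the value turned to 0.052.

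**Figure D2:**
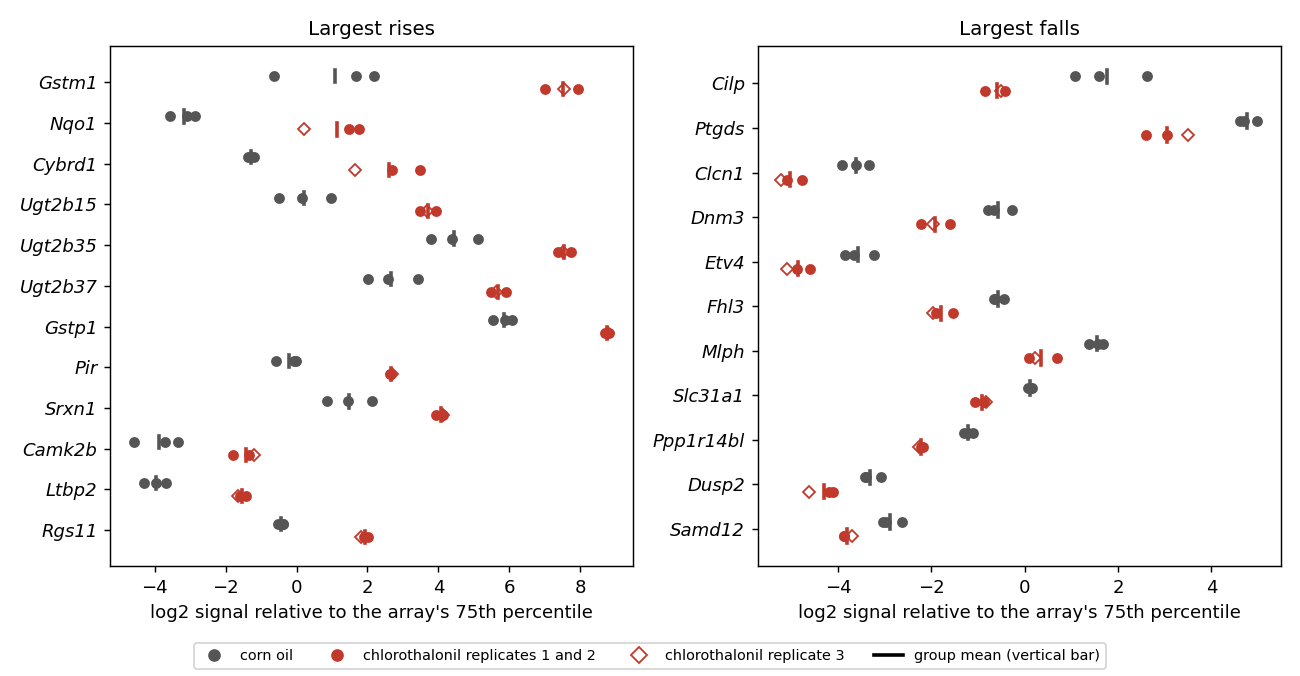
Points are the 6 arrays, as log2 signal relative to each array's 75th percentile (x axis), for the genes with the largest rises and the largest falls (y axis), with grey for corn oil, red for chlorothalonil, open diamonds for chlorothalonil replicate 3 and vertical bars for group means. For every gene drawn the arrays of the groups do not overlap, and the spread of the corn oil arrays was widest for Gstm1, from −0.64 to 2.18.

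The NRF2 and glutathione list holds genes of antioxidant defence, glutathione conjugation, NADPH supply and export that the transcription factor NRF2 is known to regulate. Of its 37 measured members, 20 rose, 0 fell and 17 did not pass, and 30 rose when adjusted over the list alone. Abcc3 and Abcc4, exporters of conjugated compounds, rose by 2.23 ± 0.10 (SE) and 2.13 ± 0.10, and Gsta3, a glutathione transferase, by 1.63 ± 0.08, with probes from 1.63 to 4.07. Tkt, an enzyme of the pentose phosphate pathway, rose by 0.94 ± 0.06. Of the 37, 35 had a log2 fold change above 0 and 2 below. The members that did not pass include Gclc, at 0.76 ± 0.60 with an adjusted p of 0.534, Hmox1, at 0.18 ± 0.27 with an adjusted p of 0.757, and Gclm, at −0.63 ± 0.61 with an adjusted p of 0.621. The corn oil arrays spread widely for Gclc (SD 1.12) and for the dim Gclm (SD 1.06), so these values do not decide whether either gene responded. Tkt, Gclc, Hmox1 and Gclm fall outside the rule for named genes and were chosen after their values were seen. The list's median log2 fold change was 0.83 and its mean 1.27, with a camera adjusted p of 2.37e-24. The adjusted p was 0.264 with an estimated correlation and 0.00183 by fry. Without corn oil replicate 3, or without any single chlorothalonil array, 10 members rose. Without corn oil replicates 1 and 2 it was 18 and 15. With no filter on dim probes, 10 members rose. On the same arrays the red blood cell transcripts had a median log2 fold change of 0.27. Of the 12 measured enzymes of the mercapturate pathway, which processes glutathione conjugates, 0 passed in limma and 2 had an unadjusted p under 0.05. Acy1, an aminoacylase, was at 0.28 ± 0.06 with an adjusted p of 0.0705.

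The lists of energy metabolism had small medians, between −0.19 and 0.22, while single members moved further. Of 34 fatty acid oxidation and PPAR alpha genes, 2 rose and 3 fell, and 12 changed when adjusted over the list alone, 3 higher and 9 lower. Acaa1a, a peroxisomal thiolase, rose by 1.28 ± 0.14 (SE), with 1 of its probes at −0.02, and Acadm, a mitochondrial acyl-CoA dehydrogenase, by 0.41 ± 0.06. Eci1, an enoyl-CoA isomerase, fell, with −0.65 ± 0.11. Hadha, a subunit of the mitochondrial trifunctional protein chosen after its value was seen, also fell, with −0.41 ± 0.07. The list's median was −0.19, with a camera adjusted p of 0.0496, and the adjusted p was 0.96 with an estimated correlation. Of 14 gluconeogenesis and ammonia genes, 3 rose, and 7 when adjusted over the list alone. Of these, Slc38a3, a glutamine transporter, rose by 1.29 ± 0.20, and pyruvate carboxylase, Pc, by 0.48 ± 0.09. That list's camera adjusted p was 0.0496, and 0.96 with an estimated correlation. Pc was also the only one of 19 citric acid cycle genes to pass, against 3 when adjusted over the list alone, in a list with a camera adjusted p of 0.04996, and 0.96 with an estimated correlation. Of 48 oxidative phosphorylation genes, 0 passed in limma and 7 had an unadjusted p under 0.05. Sdhc, a subunit of succinate dehydrogenase, was at 0.19 ± 0.06 with an adjusted p of 0.16. That list's camera adjusted p was 0.0496, and 0.96 with an estimated correlation, and its mean of 0.06 turned to −0.026 with quantile normalization. Of 27 glycolysis and hypoxia genes, the glucose transporter Slc2a1 rose by 0.47 ± 0.08 and the lactate dehydrogenase Ldha had −0.54 ± 0.10. Without chlorothalonil replicate 3 each of these 4 calls was lost, with camera adjusted p of 0.162 for fatty acid oxidation, 0.19 for gluconeogenesis and the citric acid cycle and 0.391 for oxidative phosphorylation. The fatty acid oxidation call was also lost without corn oil replicates 1 (0.0995) and 2 (0.109), and the oxidative phosphorylation call without corn oil replicates 1 (0.0535) and 3 (0.259). The gluconeogenesis and citric acid cycle calls were lost without corn oil replicate 2 (0.109 for both), corn oil replicate 3 (0.143 and 0.161) and chlorothalonil replicate 2 (0.0916 and 0.0775). With normexp, with quantile normalization and with the replicate block, the calls of gluconeogenesis, the citric acid cycle and oxidative phosphorylation were lost. Gluconeogenesis was also lost with median scaling, the citric acid cycle with the deposited table, oxidative phosphorylation with the mean of probes, and fatty acid oxidation with no filter on dim probes. In all, 6 of 29 lists passed with camera, 0 with an estimated correlation and 2 by fry for a shift in 1 direction. The 2 by fry were the NRF2 and glutathione list and the red blood cell transcripts. The red blood cell list had an estimated correlation of −0.038, below the preset 0.01, and still lost its camera call. A correlation above the preset does not account for that loss, and its cause was not tested. By fry for changes in either direction 16 passed, among them fatty acid oxidation (adjusted p of 0.00023) and gluconeogenesis (3.7e-05). In the same fry test the proximal tubule markers and the smooth muscle and juxtaglomerular markers also had 3.7e-05. The mercapturate enzymes, with 0 genes past the threshold in limma, had 0.000166. That test does not compare a list with other genes, so it does not set the lists of energy metabolism apart. With camera, 3 passed without chlorothalonil replicate 3.

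Markers of kidney cell types gave few calls. Of 30 proximal tubule markers, the phosphate and anion transporters Slc17a1 and Slc17a3 rose, by 0.96 ± 0.07 (SE) and 1.27 ± 0.14, and 28 did not pass. Adjusted over the list alone, 5 rose and 2 fell. Of 7 smooth muscle and juxtaglomerular markers, Actg2, a smooth muscle actin, was lower, at −0.59 ± 0.06, while 1 of its probes was at 0.06. None of the other cell type lists had a member past the threshold in limma. The number with an unadjusted p under 0.05 was 3 of 14 for the loop of Henle and distal tubule, where Calb1 was at −0.56 ± 0.14, and 1 of 15 for the collecting duct and medulla, where Slc4a1 was at 0.73 ± 0.21. It was 1 of 13 for podocytes, where Cdkn1c was at 0.35 ± 0.12, and 0 of 14 for endothelium, where Sox17 was at 0.24 ± 0.12. It was 1 of 20 for macrophages and myeloid cells, where Adgre1 was at −0.47 ± 0.12, and 0 of 14 for lymphocytes, where Gzmb was at 0.31 ± 0.19. It was 2 of 19 for fibroblasts and matrix, where Mgp was at 0.52 ± 0.12, 2 of 10 for fat tissue, where Cidea was at 0.58 ± 0.20, and 0 of 4 for the adrenal gland, where Fdx1 was at 0.16 ± 0.08. With camera, the macrophage and myeloid list had an adjusted p of 0.494, and of 0.00431 without corn oil replicate 1, where its mean went from −0.11 to −0.25. The endothelial list had 0.31, and 0.0399 without corn oil replicate 1 and 0.0409 without chlorothalonil replicate 3.

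Of 5 red blood cell transcripts, 0 passed in limma, 4 had an unadjusted p under 0.05 and 3 were higher when adjusted over the list alone. Their median log2 fold change was 0.27, with a camera adjusted p of 0.00648, and the adjusted p was 0.336 with an estimated correlation. The camera adjusted p was 0.191 with quantile normalization and 0.0775 without chlorothalonil replicate 2. By fry for a shift in 1 direction the list passed, with an adjusted p of 0.0071. Slc25a37, a mitochondrial iron importer of red cell precursors, was at 0.45 ± 0.09 (SE) with an adjusted p of 0.06. Globin transcripts Hbb and Hba-a1, chosen after their values were seen, were at 0.24 ± 0.07 and 0.27 ± 0.07.

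**Figure D3:**
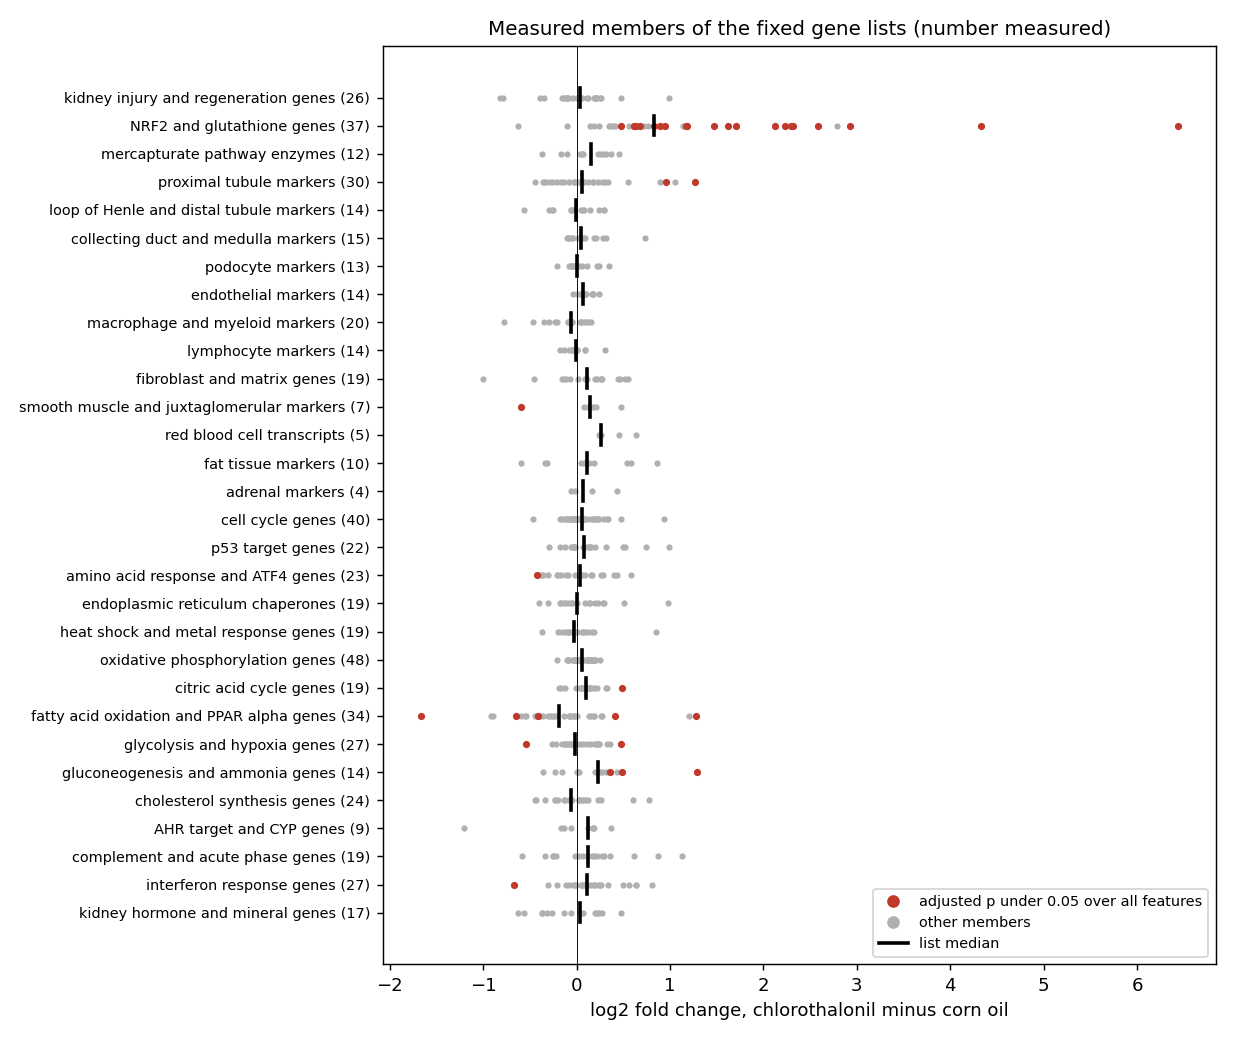
Each point is a measured member of 1 of the 30 fixed gene lists (y axis, with the number measured), placed at its log2 fold change, chlorothalonil minus corn oil (x axis). Red points passed the adjusted threshold over all features and black bars are list medians, which were 0.83 for the NRF2 and glutathione list and between −0.19 and 0.27 for the others.

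Of 26 kidney injury and regeneration genes, 0 passed in limma and 5 had an unadjusted p under 0.05. Over all 29115 features, 5748 had such a p. Prom1, a membrane glycoprotein of progenitor cells, was at −0.82 ± 0.17 (SE) with an adjusted p of 0.0689. The other members with an unadjusted limma p under 0.05 were higher but did not pass. They were Krt19 at 0.99 ± 0.32, Krt18 at 0.48 ± 0.17, Vim at 0.21 ± 0.08 and Anxa2 at 0.19 ± 0.06. Of the 26 genes, 15 had a log2 fold change above 0 and 11 below. The injury markers Havcr1 and Lcn2, chosen after their values were seen, were at 0.03 ± 0.32 and −0.04 ± 0.40. Havcr1 was dim, at −5.05 with corn oil and −5.02 with chlorothalonil, and well above background on 5 of 6 arrays. Of 40 cell cycle genes, 0 passed in limma and 2 had an unadjusted p under 0.05, with the replication licensing factor Cdc6 at 0.94 ± 0.22 and an adjusted p of 0.0966. The camera adjusted p of that list was 0.736. Without chlorothalonil replicate 1 it was 0.00319, and the list's mean went from 0.076 to 0.226. Relative to the corn oil mean, the list lay at −0.22, 0.12 and 0.33 in chlorothalonil replicates 1 to 3. Of 22 p53 target genes, 0 passed in limma, 2 had an unadjusted p under 0.05, and 2 were higher when adjusted over the list alone. Gdf15, a stress-induced secreted factor, was at 0.99 ± 0.19 with an adjusted p of 0.0562.

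Stress and immune lists gave 2 calls. Psph, an enzyme of serine synthesis, was lower, at −0.43 ± 0.06 (SE), the 1 call among 23 amino acid response and ATF4 genes. Cxcl11, a chemokine induced by interferon, was lower, at −0.67 ± 0.06, the 1 call among 27 interferon response genes. Of the 27, 19 had a log2 fold change above 0 and 8 below, with a mean of 0.143. That mean was −0.121 without corn oil replicate 1 and 0.315 without corn oil replicate 3. No member of the remaining lists passed in limma. The number with an unadjusted p under 0.05 was 6 of 19 for endoplasmic reticulum chaperones, where Sel1l was at 0.28 ± 0.06, and 2 of 19 for heat shock and metal response genes, where Cryab was at 0.85 ± 0.20. It was 6 of 24 for cholesterol synthesis, where Mvd was at −0.44 ± 0.09, and 2 of 9 for AHR targets and CYP genes, where Cyp2c23 was at 0.18 ± 0.07 and turned to −0.067 with quantile normalization. It was 2 of 19 for complement and acute phase genes, where C3 was at −0.25 ± 0.09, and 3 of 17 for kidney hormone and mineral genes, where Slc34a1 was at 0.27 ± 0.06.

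Of the genes named, 4 were past the threshold and not well above background on any array of 1 group. With chlorothalonil, Csmd1, a complement control protein, was at least 14.7-fold higher, with an adjusted p of 0.0236. Trim54, a muscle ubiquitin ligase, was at least 10.8-fold higher, with an adjusted p of 0.00667, and the lysozyme-like Lyzl1 at least 1.59-fold higher, with an adjusted p of 0.0214. Mmp20, a protease of tooth enamel, was at least 4.40-fold lower, with an adjusted p of 0.041, and its corn oil arrays spread widely, at −3.59 ± 1.49 (SD, n = 3). Of the 44 named genes past the threshold, 26, 19 and 19 stayed past it without corn oil replicates 1, 2 and 3, and 12, 13 and 16 without chlorothalonil replicates 1, 2 and 3.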

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

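The normexp setting and every count of NRF2 and glutathione genes per setting were chosen after seeing the data; the other settings were planned. The direction of each of the 44 named genes past the threshold held in every setting that tested it, except Fhl3, which ranged from −1.36 to 0.052 with 1 array left out and turned without corn oil replicate 2, where its other probe was the brighter. Among values not past the threshold in the main setting, Cyp2c23 turned to −0.067 with quantile normalization. With quantile normalization the mean of the oxidative phosphorylation list turned to −0.026, and the cause was not tested. With no filter on dim probes, 45432 features were tested and 172 changed, 78 higher and 94 lower, 108 of them at least 2-fold, with 10 NRF2 genes and 15 of the 44 named genes, and 149 of the 172 were among the 909. With normexp 1325 features changed, 589 higher and 736 lower, 142 of them at least 2-fold. With the trend and robust prior 1315 changed, 580 higher and 735 lower, 233 of them at least 2-fold. The number of lists past camera was 3 with normexp, 2 with quantile normalization and 0 with an estimated correlation. By fry, 2 lists passed for a shift in 1 direction and 16 for changes in either direction. The causes of these moves were not tested. Quantile normalization, median scaling, the value table, kept outlier spots, the mean of probes and the filter on all arrays left the number of changed features between 803 and 925. Leaving out 1 array gave 112 to 388 changed features, 52 to 198 higher, 60 to 190 lower and 83 to 176 changed at least 2-fold. It gave 3 to 7 lists, 10 to 18 NRF2 genes and 12 to 26 of the named genes; fewer arrays leave less power.

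With the replicate number as a block, 0 features changed in limma, 0 higher, 0 lower and 0 at least 2-fold, with 5271 at an unadjusted p under 0.05. This fit kept 0 NRF2 genes, 0 named genes and 3 lists. Arrays with the same number deviated from their group means with correlations across features of 0.10, 0.02 and 0.05. Those with different numbers had correlations between −0.09 and 0.053, and not every array correlated best with its own number. Values this small, on 3 arrays per group, do not settle whether the numbers pair the samples. The slide as a block was not run, because each slide held 1 group. Signal over background limits the genes named as bounds and the 84 changed features that were not well above background on every array.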

Other observations

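The tests of families by symbol and of the C_CA probes, and all the weighing tests below except that of the families without listed genes, were chosen after the results were seen. Among 199 groups of at least 8 measured genes that share the start of their symbol, 4 passed with camera: the UDP-glucuronosyltransferases (adjusted p of 9.4e-08), the ABCC transporters (0.00043), the aldehyde dehydrogenases (0.0238) and the aldo-keto reductases (0.0313). The smallest adjusted p was 0.875 with an estimated correlation. Of 9 UGT genes, 6 rose, 1 of them in the NRF2 list, among them Ugt1a1 by 1.33 ± 0.13 (SE) and Ugt1a2 by 1.56 ± 0.09, which share exons with Ugt1a6. Of 17 aldehyde dehydrogenases, 0 of them in that list, 3 rose: Aldh1l1, a folate enzyme, by 1.95 ± 0.07, Aldh3b1 by 1.50 ± 0.24, and Aldh1a1 by 0.61 ± 0.06. Of 9 ABCC transporters 4 rose, 3 of them listed genes and the other Abcc1, by 0.62 ± 0.06. Of 13 aldo-keto reductases 1 rose, the listed Akr7a3. With the listed genes left out, the smallest camera adjusted p over these 4 families was 5.86e-08, for the UGT genes. With an estimated correlation the adjusted p was 0.0281 for the UGT genes and 0.0362 for the aldehyde dehydrogenases, and 0.193 for the ABCC transporters and 0.13 for the aldo-keto reductases. The families were picked on the same arrays because they passed, so this test does not decide whether a rise beyond the listed genes is general. In 3 of the 9 other splits of the arrays, which keep part of the group difference, a family also passed, with 0.000254 as the lowest value.

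Probes with identifiers that begin with C_CA, which the files pair with no gene, changed more often than other features. Of 629 tested, 39 changed, 35 higher and 4 lower, which is 6.2% against 3.05% of other features. Within 5 classes of brightness the odds ratio was 1.99 (95% interval 1.39 to 2.79, exact Mantel-Haenszel test). That interval takes the probes as independent, while C_CA probes were not merged by gene. C_CA_F0511 and C_CA_F0512 had nearly the same values, at 1.55 and 1.57, and C_CA_F0440 lay close to Gstm1, which was at 6.43. Some may repeat 1 transcript, which was not tested, so the interval may be too narrow. The interval lies above 1 but includes 1.5, the ratio set as the bound, so a class of transcripts that responds more often may be behind it but stays a hypothesis. The 3 largest rises were C_CA_F0440 at 6.36, C_CA_F0078 at 3.78 and C_CA_B0070 at 3.21, all singled out after their values were seen.

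The rise of the NRF2 and glutathione genes was set against 3 technical explanations. A slide or scan difference that moves all probes alike is argued against by the signals before scaling between arrays. There the median difference over all features was −0.063 ± 0.051 (SE over arrays), against 0.76 for the list's median. Shared signal in the GST, UGT and ABCC families as the whole cause is argued against by the 25 listed genes outside them, with a median of 0.68 and 12 higher, and a larger share of proximal tubule by a marker median of 0.058. A slide difference of single probes cannot be told apart from treatment, and a response to chlorothalonil stays a hypothesis.

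Chlorothalonil replicate 3 carries the name of another compound in 1 label. That it came from a corn oil animal is argued against by the NRF2 list, whose mean on this array lay 1.24 above the corn oil mean, against 1.39 and 1.17 on the other two treated arrays. This holds only if the slide did not raise these probes, since the array lay on the same slide as those arrays. Another compound with the same response may still fit, and it cannot be told apart from chlorothalonil here. The largest root mean square difference of this array from the other treated arrays was 0.351, below the 0.406 of the closest corn oil pair. The shared slide could also bring the treated arrays closer together.

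Features without a gene symbol fell more often than they rose, 448 of 654, or 68.5%, while 32.5% of changed features with a symbol fell. With scaling to the array median the share without a symbol was 58.8%, and with quantile normalization 66.9%, so the scaling may account for part of it and does not decide the rest. The 8 spike-in probes well above background, which match no rat RNA, had a median log2 difference of −0.13 between the chlorothalonil and corn oil slides. They ranged from −0.34 to 0.05, and 7 of the 8 were lower on the chlorothalonil slide. The difference was lower for dimmer probes, with a rank correlation to brightness of 0.786 (p = 0.0279), a test chosen after the values were seen. That order rests on the dimmest probes, at −0.342 and −0.208, and on the brightest, at −0.1 and 0.048. From dimmer to brighter, those of middle brightness had −0.116, −0.111, −0.149 and −0.186. Dim features could still lie lower by slide, and how much of the falls this makes up was not tested. Over all 17189 features without a symbol, dim or bright, the median log2 fold change was −0.012. The number of slides that held both groups was 0, so a slide difference of single probes cannot be told apart from treatment.

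The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. Each of the 9 other splits put 2 arrays of one group with 1 of the other. The difference between the real groups then widens the spread within each side, and part of it stays in the contrast. Few changed features were therefore to be expected in them, and they are no reference free of the group difference. The real split gave 909 changed features and the highest other 2. For features higher it was 378 against 2, for features lower 531 against 0, and for those changed at least 2-fold 211 against 2. In each of these, 1 of the 10 splits, the real one, gave a result as large. For lists past camera it was 6 against 11, and 7 of the 10 splits gave as many, so the number of lists called with a preset correlation does not set the real split apart. The NRF2 and glutathione list had 20 members past the threshold in the real split and 0 in the others. Its camera test passed in 7 of the 9 other splits, with a lowest adjusted p of 1.2e-05. Its absolute mean log2 difference reached 0.586 in those splits, against 1.27 in the real one.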
